A study of Arabidopsis thaliana with 12 samples.

How the data were processed

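RNA bound to tagged ribosomes was sequenced from leaves of Arabidopsis thaliana ecotype Shahdara. Per the labels' protocols, plants expressing an RPL18 protein with a His6 and FLAG tag were 5 weeks old, leaves were inoculated with tobacco mosaic virus (TMV, 1 mg/ml) or with sterile water, and the inoculated leaves were frozen 6 days later. Polysomes were pulled down with anti-FLAG beads, the RNA was purified on columns, and Illumina TruSeq libraries were made. The tag was driven by 1 of 3 promoters, named p35S, pSUC2 and pSULTR22. Each of the 6 groups of promoter line and treatment had 2 biological replicates, which per the labels were grown in different months; the month of a given library is not stated.

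The authors deposited 1 table per library with 28642 genes. Per the file headers, each table gives for every gene the count of exon reads, the count of all gene reads (introns included) and an RPKM value. The submitters' processing notes name CASAVA 1.8.2 and the TAIR10 build, with no role for either. The read mapper, the treatment of reads that map to several places, the strand rule and the filters are not recorded in the labels or headers. The deposited counts are whole numbers with no normalization. The deposited RPKM values are exon reads divided by gene length and by a library total, which was checked by dividing one by the other, gene by gene, with a largest relative deviation of 1.8e-09 between libraries. In 8 of the 12 deposited tables some genes with 0 exon reads carry an RPKM above 0, and in the other 4 none do, so the tables take 2 forms; RPKM was therefore not used to compare genes, and it served only to work out the mapped reads of each library. Genes of the nucleus (28496) and of the mitochondrion (146) were listed; chloroplast genes and the viral genome are not analysed here.

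Exon reads were the values tested. Their total per library ran from 4015230 to 32093368, and the lowest totals belonged to infected leaves. The number of mapped reads behind each library was worked out from the RPKM of genes without introns, and the share of mapped reads that fell on exons was taken from it. A gene was tested if it passed edgeR's filterByExpr over the groups, which left 19697 genes and took out 8945. Counts were scaled by TMM factors and fitted with edgeR's quasi-likelihood model, with 1 coefficient for each of the 6 groups over all 12 libraries, so that all comparisons share 1 estimate of the spread (6 residual degrees of freedom before shrinkage). The standard error of a log2 fold change (SE) was taken as its size divided by the square root of the F statistic. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. Normalized counts (CPM) are exon reads over the scaled library total, given as mean ± SD. With 2 libraries per group, p-values measure the spread between these libraries only.

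The comparisons were TMV against mock in each line, the mean of those 3 differences, each pair of lines in mock leaves, and the difference in TMV effect between each pair of lines. The design, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. By that rule the text names the 6 highest and 6 lowest called genes of a comparison that had a symbol, a mean of at least 5 CPM and no overlap between the groups, up to 4 members of each list with the smallest p whether or not they passed, the genes SUC2, SULTR2;2 and RPL18 as checks of promoter and tag, and up to 6 called genes of each interaction. Symbols came from NCBI's RefSeq annotation of the same genome, which held 28009 of the 28642 genes and gave a symbol for 10255. Coordinates are those of the deposited tables.

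The 25 gene lists were the markers of companion cells and sieve elements, phloem parenchyma, xylem and procambium, bundle sheath, epidermis and guard cells, with genes of photosynthesis, aliphatic glucosinolates, indolic glucosinolates and camalexin, salicylic acid defence, jasmonate, Aux/IAA and auxin response, RNA silencing, tobamovirus multiplication, callose and plasmodesmata, sugar transport and invertase, sulfate uptake and assimilation, heat shock and chaperones, endoplasmic reticulum chaperones, senescence, the circadian clock, hypoxia, early wounding and handling, cytosolic ribosomal proteins and the tagged ribosomal protein family. Of 340 members, 11 were dropped because the reference did not pair the symbol with the code; the last list kept a single member and was not tested, so 24 lists were. Each list was tested with camera of limma on log2 CPM (prior count 2) with its preset correlation of 0.01, again with camera using a correlation estimated from the data, and with fry; p-values were adjusted over the lists of a comparison. Differences of a single value between groups were tested with exact two-sided permutation tests.

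The tests were run first on simulated data made from the real means and library sizes, with 200 genes changed by known folds. In the simulated TMV comparison of pSUC2 (19411 genes), edgeR found 0%, 6%, 48% and 80% of the 50 genes changed 2-, 4-, 8- and 16-fold, with 1 false call, and DESeq2 found 0%, 46%, 82% and 90% with 32 false calls. In the simulated average over the lines (19398 genes) edgeR found 8%, 70%, 96% and 98% with 10 false calls, and DESeq2 28%, 86%, 98% and 98% with 59. A list of 17 RNA silencing genes raised 2-fold in the average passed with the preset correlation (adjusted p = 6.49e-20), with the estimated correlation (adjusted p = 0.0017) and with fry (adjusted p = 0.000259), and 0 of the other lists were called. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often the list tests make false calls where members of a list vary together.

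The alternatives chosen beforehand were DESeq2's size factors or upper-quartile factors in place of TMM, no filter, a filter of 5 CPM in 2 libraries, DESeq2's Wald test, only the groups compared in the fit, the replicate number as a block over all lines or within each line, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were counts of all gene reads, thinning to the smallest library, limma-voom with library weights, a clock gene score as a covariate, the pSUC2 libraries left out, the infected libraries of replicate 2 only, the 3 mock libraries with a clock gene score above 0 left out, and a crossed block. The clock gene score of a library was the mean log2 CPM of PRR9, PRR7 and PRR5 minus that of TOC1 and BOA. The crossed block was the replicate number with the numbers of the p35S mock libraries exchanged, a pairing read from the data. No pair of libraries agreed within sampling noise (lowest chi-square 13.6 per gene), so none was taken as a repeat of another. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.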

Results

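The series measured which messenger RNAs were carried on ribosomes in leaves infected with tobacco mosaic virus (TMV), a positive-strand RNA virus that moves between organs through the phloem. Plants carried an epitope-tagged ribosomal protein L18 (RPL18), so that ribosomes and the transcripts on them could be pulled down from the cells in which a chosen promoter is active; the sequenced RNA is called the translatome. The p35S line used the cauliflower mosaic virus 35S promoter, active in most leaf cells. The pSUC2 line used the promoter of SUC2, the sucrose transporter of companion cells, and the pSULTR22 line that of SULTR2;2, a sulfate transporter of vascular tissue; the labels describe the RNA of both lines as from leaf phloem. Each of the 3 lines was sampled after TMV and after mock inoculation with 2 biological replicates, 12 libraries in all. In p35S the infected libraries held 25665123 and 8552010 exon reads and the mock libraries 32093368 and 24236158. In pSUC2 these totals were 12930807 and 4015230 after TMV and 18822090 and 30924158 in mock. In pSULTR22 they were 10987774 and 7944550 after TMV and 21207007 and 24383902 in mock. Infected libraries were shallower than mock libraries (exact two-sided permutation p = 0.01082, 6 against 6). They also had a lower share of mapped reads on exons (68.3 ± 15.1% against 92.5 ± 4.59%, exact permutation p = 0.004329, adjusted p = 0.00577 over 4 such measures).

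Replicates of a group were far apart. The common biological coefficient of variation was 0.452, and pairs of the same group lay between 0.376 and 0.533. Of the 60 pairs from different groups, 19 were closer than the closest pair of replicates. No library (0 of 12) was nearest to its own replicate, 10 were nearest to a library of the same treatment and 1 to a library of the same line. The 3 mock libraries p35S replicate 1, pSUC2 replicate 2 and pSULTR22 replicate 2 differed from each other by 0.131 to 0.151, and the infected p35S replicate 1 lay 0.157 to 0.193 from them.

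**Figure D1:**
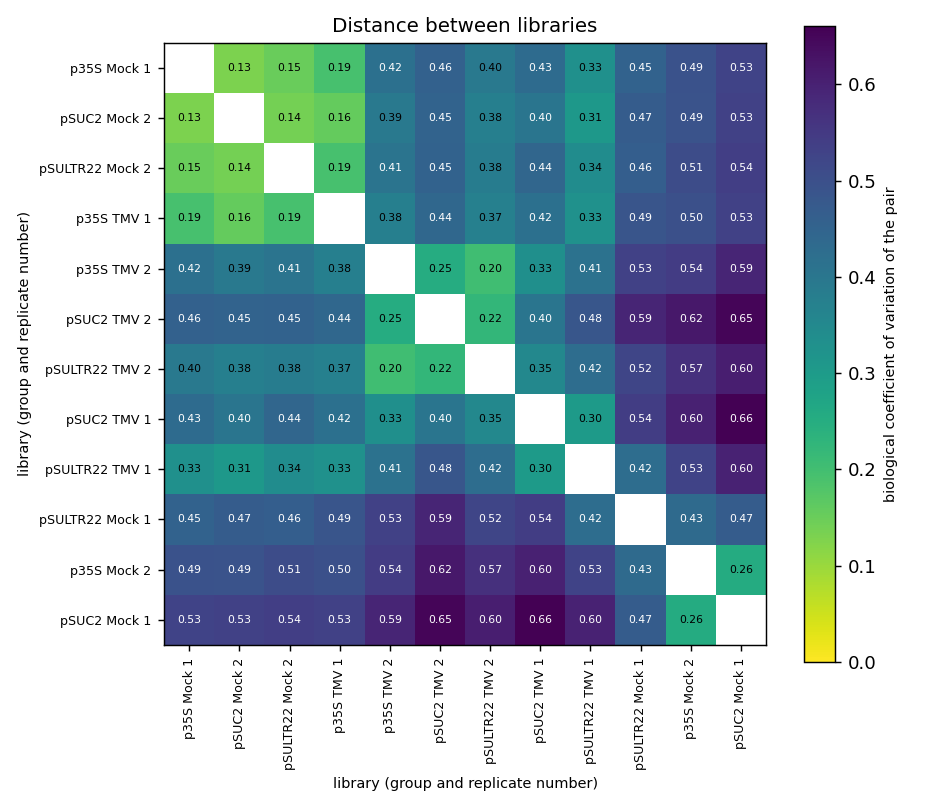
Distance between each pair of the 12 libraries as the biological coefficient of variation over the tested genes; both axes list the libraries by group and replicate number, and darker cells are farther apart. The mock libraries p35S 1, pSUC2 2 and pSULTR22 2 sit at 0.13 to 0.15 from each other, while replicates of the same group sit between 0.376 and 0.533.

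The genes whose promoters drove the tag were read first, because a pull-down from the cells that express a gene should hold more of its transcript. SULTR2;2 (AT1G77990, chromosome 1, 29317899 to 29323352) stood at 37.3 ± 12.4 CPM in the pSULTR22 libraries (SD, n = 4), against 15.6 ± 4.03 in p35S and 15.9 ± 3.46 in pSUC2. All 4 pSULTR22 libraries (24.2 to 53.0 CPM) lay above all others, the smallest p that 4 against 4 can give (exact permutation p = 0.02857, adjusted p = 0.1286 over 9 tests of 3 genes). SUC2 (AT1G22710, chromosome 1, 8030641 to 8033117) was not higher in the libraries labelled pSUC2 (62.3 ± 23.4 CPM) than in p35S (83.7 ± 29.1 CPM, exact permutation p = 0.3143). Its highest values were in pSULTR22, at 927 and 191 CPM in mock and 728 and 63.1 CPM after TMV, a spread too wide to separate the lines (477 ± 416 CPM, exact permutation p = 0.1143 against p35S, adjusted p = 0.2057). RPL18 (AT3G05590, chromosome 3, 1621457 to 1623014), to which reads of the tagged transgene would map, stood at 886 ± 466 CPM in pSULTR22, 479 ± 94.0 in p35S and 481 ± 128 in pSUC2, and no line differed from another after adjustment. An antisense gene, AT1G77992, overlaps SULTR2;2, and the counting is not stated to use strand, so reads of this pair cannot be told apart.

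**Figure D2:**
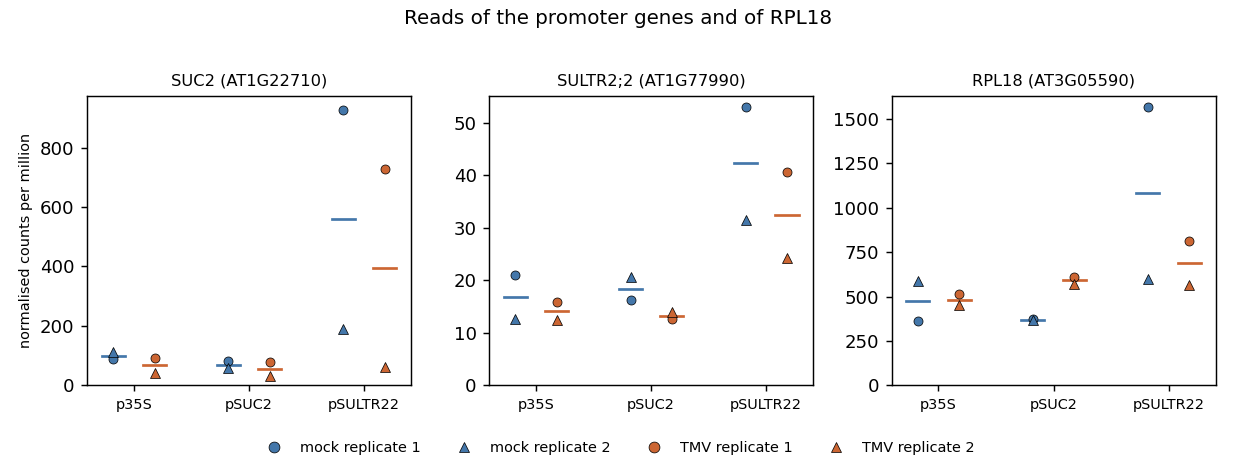
Normalized counts (CPM) of SUC2, SULTR2;2 and RPL18 (vertical axes, linear from 0) in the 3 lines, with mock libraries in blue, infected libraries in orange, circles and triangles for replicates 1 and 2 and bars for group means. SULTR2;2 lies between 24.2 and 53.0 in pSULTR22 and below 21.2 elsewhere, while SUC2 lies below 113 in both p35S and pSUC2.

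Infected and mock leaves were compared first on average over the 3 lines, 6 libraries against 6. With edgeR, 8 of 19697 genes rose after TMV and 0 fell. Among them were 3 basic helix-loop-helix transcription factors of the iron deficiency response. These were bHLH38 (70.7 ± 31.9 against 3.43 ± 1.95 CPM in mock, log2 fold change 4.34, SE 0.47, adjusted p = 0.01564), bHLH39 (18.22 ± 11.6 against 1.12 ± 0.570 CPM, 3.92, SE 0.47) and BHLH101 (41.8 ± 32.2 against 2.67 ± 1.31 CPM, 3.86, SE 0.50). FRO3, a mitochondrial ferric chelate reductase, rose by 2.33 (SE 0.32, 97.3 ± 23.7 against 19.5 ± 8.09 CPM), and the germin-like gene GER1 (AT1G72610) by 2.92 (SE 0.41, 449 ± 259 against 52.9 ± 15.3 CPM). ERD2 (AT1G56410), a cytosolic heat shock protein of the HSP70 family, had 31 to 731 reads in the infected libraries and 0 to 3 in the mock libraries (adjusted p = 0.02344). Its fitted fold depends on the prior count, and reads shared with other HSP70 genes are possible. The other 2 genes have no symbol and fall outside the naming rule, so they were chosen after their values were seen: AT1G13609, a defensin-like gene (3.56, SE 0.39, 43.6 ± 18.8 against 3.54 ± 1.65 CPM), and AT4G17245, a RING/U-box protein gene (2.52, SE 0.36, 73.7 ± 35.4 against 12.2 ± 4.47 CPM). The adjusted p of the other 6 genes lay between 0.01564 and 0.04473. For all 8 genes the lowest infected library stood above the highest mock library, which chance would give in either direction with a probability of 0.002165 for a gene fixed in advance. These genes were picked by that very difference, so this is no test of them. The infected p35S replicate 1 was the lowest infected library for all 8.

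The number of genes called on average depended on the setting. The counts with a replicate block within each line and with the crossed block also differed and are given below with the processing choices. At an unadjusted p under 0.05 there were 4239 genes, where 985 would be expected by chance. Here and below, that number assumes evenly spread p-values, which libraries that fall into clusters need not give. A regrouping within the lines that set 3 infected and 3 mock libraries against the rest gave 3645 such genes. The excess over 985 is therefore no measure of a response to the virus. DESeq2 called 1471 (738 higher and 733 lower), edgeR without a filter 429, edgeR with a clock gene score 18, and limma-voom with library weights 4. Leaving out p35S TMV replicate 1 raised the count to 19. It was 3 without p35S TMV replicate 2, 5 without pSULTR22 TMV replicate 2, 3 without p35S mock replicate 1, 1 without p35S mock replicate 2, and 0 without any 1 of the other 7 libraries. It was also 0 with all pSUC2 libraries left out (1441 genes at an unadjusted p under 0.05) and with the infected libraries of replicate 2 only (4486 genes). The mock libraries p35S 2, pSUC2 1 and pSULTR22 1 had high clock gene scores, and without these 3, which leaves 1 mock library per line, the count was 0 (2039 genes), with bHLH38 at 4.5 (SE 0.52) and FRO3 at 1.93 (SE 0.33).

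The 8 genes were also read line by line, where none passed the adjusted threshold. The log2 fold change of bHLH38 was 4.16 (SE 0.81) in p35S, 4.65 (SE 0.83) in pSUC2 and 4.21 (SE 0.81) in pSULTR22. FRO3 gave 2.12, 2.05 and 2.82 in the same order, AT1G13609 3.44, 3.94 and 3.3, and AT4G17245 2.13, 2.98 and 2.46. Among the genes given here, which leave out bHLH39 and ERD2 (AT1G56410), the spread over the lines was wider for 2. These were BHLH101, with 2.38 (SE 0.81), 4.43 (SE 0.89) and 4.76 (SE 0.91), and GER1 (AT1G72610), with 2.06, 3.79 and 2.92. The differences between lines did not pass the test for any of the genes given (edgeR adjusted p = 1 for each).

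**Figure D3:**
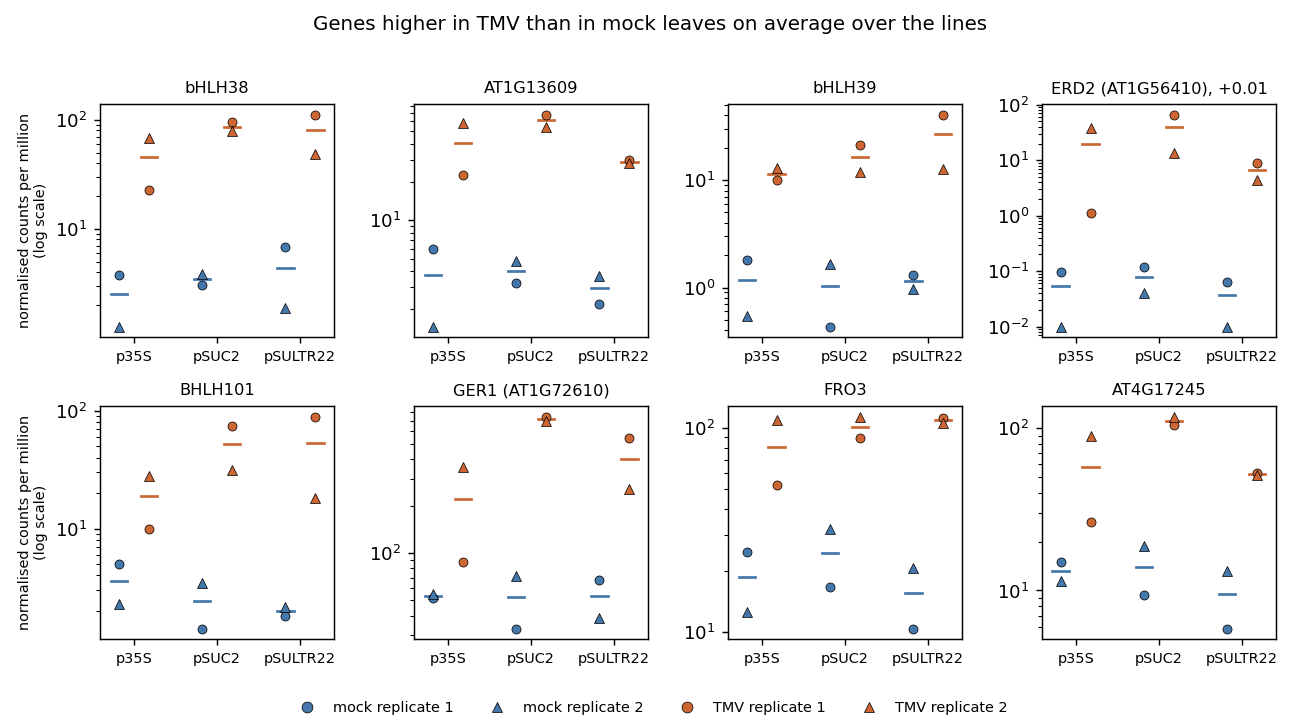
Normalized counts (CPM), on log axes, of the 8 genes that rose on average, in mock (blue) and infected (orange) libraries of the 3 lines, with circles and triangles for replicates 1 and 2 and bars for group means. Every infected library lies above every mock library in each panel; 0.01 was added for ERD2 (AT1G56410), which had 0 reads in some mock libraries.

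Of the gene lists, 3 stood apart from the other genes on average over the lines, and each lost its call with an estimated correlation. All 15 aliphatic glucosinolate genes lay lower after TMV (median log2 fold change -0.83, camera adjusted p = 0.0306, adjusted p = 0.884 with an estimated correlation). Among them were MYB29, a regulator of the pathway (-1.82, SE 0.40), the sulfotransferase gene SOT17 (-1.79, SE 0.57), MYB76 (-1.15, SE 0.45) and CYP83A1 (-1.0, SE 0.40). Over all genes 0 members fell, and MYB29 did adjusted over the list alone. The median was -0.34 without pSULTR22 mock replicate 1. The level of the list, relative to its mean, was 0.42, 0.74 and 2.01 in the 3 mock libraries with high clock gene scores and -0.46, -0.69 and -0.16 in the other mock libraries, against -0.88 to 0.46 in the infected libraries. Without those 3 libraries the median was 0.09 (camera adjusted p = 0.5524), so the lower level after TMV rested on them. Of 17 RNA silencing genes 15 lay lower (median -0.45, camera adjusted p = 0.0306, adjusted p = 0.884 with an estimated correlation, fry for change in either direction, adjusted p = 0.0441). The 4 with the smallest p were the Argonaute gene AGO7 (-0.91, SE 0.24, the only one to pass adjusted over the list alone), the Dicer-like genes DCL3 (-0.89, SE 0.28) and DCL1 (-0.83, SE 0.27), and the small RNA methyltransferase HEN1 (-0.61, SE 0.23). Of 42 photosynthesis genes 28 lay higher (median 0.27, camera adjusted p = 0.0354, adjusted p = 0.884 with an estimated correlation), led by RBCS1A (1.33, SE 0.42) and PSAE1 (1.1, SE 0.35). That median was 0.06 without pSUC2 TMV replicate 1 and 0.56 without pSULTR22 mock replicate 1, and the near-identical RBCS and LHCB genes can share reads. Without the 3 mock libraries with high clock gene scores the medians were -0.26 for RNA silencing (camera adjusted p = 0.05478) and 0.56 for photosynthesis genes (camera adjusted p = 3.971e-06, adjusted p = 0.6601 with an estimated correlation). The infected libraries, in which these lists moved, were also those with the lower share of mapped reads on exons (68.3 ± 15.1%).

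Other lists were called neither way by camera on average, but single members passed when adjusted over the list alone. In the jasmonate list 3 of 22 genes were higher: the vegetative storage protein genes VSP1 (1.93, SE 0.44, 93.6 ± 54.3 against 24.3 ± 8.08 CPM) and VSP2 (2.22, SE 0.62) and the defensin gene PDF1.2 (2.17, SE 0.53). The epidermis list had 3 of 9 higher, the lipid transfer protein genes LTP2 (1.33, SE 0.34) and LTP1 (1.09, SE 0.37) and PDF1 (1.3, SE 0.34). In the heat shock list HSP70 (2.48, SE 0.62) and HSP17.6A (2.55, SE 0.70) were higher, the second with at most 1.45 CPM in any library. Among 24 companion cell and sieve element genes, the potassium channel gene AKT2 (-1.67, SE 0.35, 11.1 ± 2.17 against 35.3 ± 16.8 CPM) and GLR3.3 (-1.19, SE 0.32) were lower and OPT3, which carries iron in the phloem, was higher (0.95, SE 0.28, 395 ± 156 against 201 ± 36.5 CPM). Among 10 indolic glucosinolate and camalexin genes, CYP71A13 of the camalexin pathway was higher (1.48, SE 0.36), and MYB34 (-1.23, SE 0.32), CYP83B1 (-0.98, SE 0.32) and CYP79B2 (-1.24, SE 0.46) of the indolic branch were lower. APR2, an enzyme of sulfate reduction, was lower (-1.70, SE 0.42) in a list of 11 sulfate uptake and assimilation genes with a median of -0.37. In the phloem parenchyma list (median -0.49) the sugar transporter gene SWEET13 (-2.53, SE 1.02) and UMAMIT18 (-1.40, SE 0.50) were lower, while SWEET12 was higher (0.98, SE 0.30). Without the 3 mock libraries with high clock gene scores 3 genes of that list were measured, with a median of 0.58. In the senescence list SEN1 (AT4G35770) was higher (0.90, SE 0.26) and the transcription factor gene NAP lower (-1.47, SE 0.43). With fry for change in either direction, the epidermis list and the companion cell list also passed (adjusted p = 0.0488 each), and each held members that went both ways.

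The remaining lists had neither a camera call nor a member that passed adjusted over the list alone on average. The 25 salicylic acid defence genes had a median of 0.09 (camera adjusted p = 0.371), with AIG1 at -0.88 (SE 0.34), ICS1 at -0.86 (SE 0.40) and PR5 at 0.68 (SE 0.38). That median ran from -0.14 (without pSUC2 mock replicate 1) to 0.46 (without p35S mock replicate 1), and it was -0.27 with 19 of 25 lower (camera adjusted p = 0.05478) without the 3 mock libraries with high clock gene scores. The 4 tobamovirus multiplication genes, host factors of virus replication, had a median of -0.07, with TOM2B at 0.77 (SE 0.29), TOM1 at -0.29 (SE 0.21) and TOM3 at -0.14 (SE 0.21). The medians of 22 Aux/IAA and auxin response genes, a family of which some members bind the TMV replicase, and of 12 callose and plasmodesmata genes were -0.30 and -0.17, with IAA17 at -0.97 (SE 0.32) and the callose synthase gene CALS3 at -0.90 (SE 0.26). The medians were 0.52 for 9 cytosolic ribosomal protein genes (camera adjusted p = 0.0505), 0.85 for 9 early wound and handling genes, -0.22 for 11 clock genes, -0.01 for 7 hypoxia genes, 0.02 for 8 endoplasmic reticulum chaperone genes and 0.01 for 15 sugar transport and invertase genes. They were 0.02 for 13 xylem and procambium genes, -0.10 for 4 bundle sheath genes and -0.02 for 5 guard cell genes. The cytosolic ribosomal protein list was filled by matching a fixed wording in the annotation, which gave 11 genes. Genes described in other words are not in it, so its median does not describe the whole family. RPL18 stood at 0.02 (SE 0.30). It alone of its family was kept, because the reference did not pair the other symbols with their codes. The early wound median was -0.09 without pSULTR22 TMV replicate 1, and the clock median was -1.41 without pSUC2 TMV replicate 2 and 0.29 without the 3 mock libraries with high clock gene scores. That score is made from members of the clock list, so the last median is no test. Without those 3 the sugar transport and invertase genes had a median of 0.56 (camera adjusted p = 0.02522, adjusted p = 0.6601 with an estimated correlation).

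**Figure D4:**
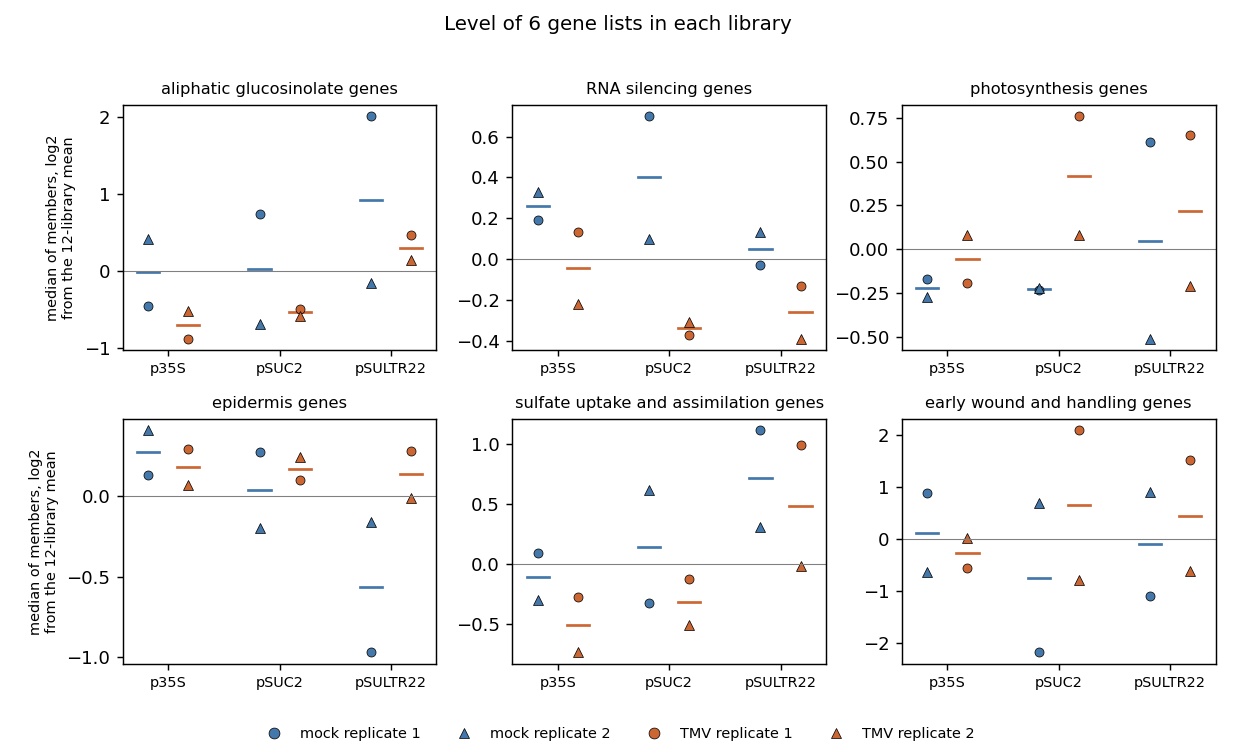
Level of 6 gene lists in each library, as the median over members of the log2 CPM minus its mean over the 12 libraries (vertical axes); mock in blue, TMV in orange, circles and triangles for replicates 1 and 2, bars for group means. The aliphatic glucosinolate genes stand highest in pSULTR22 mock replicate 1, and in several panels replicates of a group lie farther apart than the group means.

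In the p35S line, which samples most leaf cells, the camalexin gene CYP71A13 was higher after TMV (24.0 ± 10.7 against 3.88 ± 2.22 CPM, SD, n = 2 each, log2 fold change 2.62, SE 0.65). It was the only member of any list to pass adjusted over the list alone. The senescence regulator NAP stood at 4.78 ± 1.66 against 27.8 ± 23.4 CPM (-2.52, SE 0.76). Aliphatic glucosinolate genes lay lower in 14 of 15 (median -0.66, camera adjusted p = 0.0327, adjusted p = 0.870 with an estimated correlation), with MAM3 at -1.03 (SE 0.64), SOT17 at -1.50 (SE 0.97) and MYB29 at -1.0 (SE 0.67). Senescence genes lay lower in 7 of 9 (median -0.94, camera adjusted p = 0.0327, adjusted p = 0.870 with an estimated correlation), with NYE1 at -1.31 (SE 0.61) and ORE1 at -1.24 (SE 0.58). AKT2 (-1.70, SE 0.59), IAA1 (-1.55, SE 0.62), VSP1 (1.87, SE 0.76) and the cellulose synthase gene IRX5 (1.1, SE 0.42) had the smallest p of their lists. edgeR called 0 genes, with 424 at an unadjusted p under 0.05 where 985 would be expected by chance, and DESeq2 called 9, all higher. Without p35S mock replicate 1 the aliphatic and senescence medians were -1.0 and -1.37, and without p35S mock replicate 2 they were -0.22 and -0.29.

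In the pSUC2 line photosynthesis genes lay higher after TMV in 31 of 42 (median 0.53, camera adjusted p = 0.00485, adjusted p = 0.896 with an estimated correlation), with the photosystem I subunit gene PSAE1 at 3563 ± 558 against 895 ± 459 CPM (1.99, SE 0.62) and PSAO at 1.57 (SE 0.67). RNA silencing genes lay lower in 15 of 17 (median -0.82, camera adjusted p = 0.00809, adjusted p = 0.896 with an estimated correlation, fry for change in either direction, adjusted p = 0.0497). DCL3 stood at 3.79 ± 0.119 against 11.1 ± 3.32 CPM (-1.56, SE 0.49), HEN1 at -1.25 (SE 0.42), DCL1 at -1.23 (SE 0.47) and SGS3 at -0.85 (SE 0.38). The xylem and procambium list passed fry for change in either direction (adjusted p = 0.0444) with 9 of 13 genes lower, among them VND6 (-2.85, SE 0.84), TMO5 (-3.06, SE 1.18) and HB15 (-1.22, SE 0.49). LTP2 (2.26, SE 0.61) and SEN1 (AT4G35770, 53.5 ± 0.217 against 12.5 ± 6.52 CPM, 2.09, SE 0.47) passed adjusted over their lists alone. Of the markers of companion cells, AKT2 stood at -2.06 (SE 0.61), GLR3.3 at -1.59 (SE 0.57) and NAKR1 at 1.89 (SE 0.76). edgeR called 0 genes, with 2859 at an unadjusted p under 0.05 (1027 higher and 1832 lower) where 985 would be expected by chance, and DESeq2 called 164, 82 each way. The infected libraries of this line had the lowest shares of mapped reads on exons, 47.5 and 55.5%. Without pSUC2 TMV replicate 1 the photosynthesis median was -0.01 and without replicate 2 it was 0.89, and without pSUC2 mock replicate 1 the RNA silencing median was -0.41 and the xylem and procambium median 0.18.

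In the pSULTR22 line all 15 aliphatic glucosinolate genes lay lower after TMV (median -1.02, camera adjusted p = 0.00451, adjusted p = 0.839 with an estimated correlation), led by MYB29 (9.29 ± 3.09 against 61.9 ± 59.4 CPM, -2.73, SE 0.71), SOT17 (-2.55, SE 1.01) and MYB28 (-1.46, SE 0.65). MYB34, which regulates the indolic branch, stood at -2.33 (SE 0.58), and MYB29 and MYB34 passed adjusted over their lists alone. Epidermis genes lay higher in 8 of 9 (median 0.49, camera adjusted p = 0.00219, adjusted p = 0.839 with an estimated correlation), with PDF1 at 1.46 (SE 0.59), LTP2 at 1.47 (SE 0.60) and LTP1 at 1.3 (SE 0.65). PDF1.2 (2.94, SE 0.94), OPT3 (1.16, SE 0.49) and AGO7 (4.57 ± 0.153 against 10.5 ± 0.106 CPM, -1.20, SE 0.42) had the smallest p of their lists. edgeR called 0 genes, with 493 at an unadjusted p under 0.05 where 985 would be expected by chance, and DESeq2 called 12 (11 higher and 1 lower). The aliphatic median rested on pSULTR22 mock replicate 1. It was 0.53 without that library and -1.73 without pSULTR22 mock replicate 2, without which the epidermis median was 1.14. The photosynthesis median was 0.09 with all libraries and 0.89 without pSULTR22 mock replicate 1, and the sugar transport median was 0.13 and 0.82. Only 1 mock library, replicate 2, was then left, so these medians rest on that library and test nothing. Its photosynthesis level was the lowest of all 12 (-0.51), while its sugar transport level was -0.12.

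The lines were compared in mock leaves to ask which transcripts each promoter's pull-down held in different amounts. Between pSUC2 and p35S, markers of companion cells did not pass as a list (median 0.03, camera adjusted p = 0.233). Of its members FTIP1 was at 167 ± 184 against 22.4 ± 12.3 CPM (2.89, SE 1.19), APL at 0.43 (SE 0.45) and SUC2 at -0.52 (SE 0.97, SD, n = 2 each). All 9 senescence genes lay lower in pSUC2 (median -0.48, camera adjusted p = 1.68e-07, adjusted p = 0.177 with an estimated correlation), with SEN1 (AT4G35770) at 12.5 ± 6.52 against 32.0 ± 0.721 CPM (-1.35, SE 0.46). Early wound genes lay lower in 7 of 9 (median -0.43, camera adjusted p = 4.13e-05, adjusted p = 0.498 with an estimated correlation). Aux/IAA genes lay lower in 18 of 22 (median -0.18, adjusted p = 0.000667 and 0.177 with an estimated correlation). So did 8 of 8 endoplasmic reticulum chaperone genes (median -0.16, adjusted p = 0.023 and 0.602 with an estimated correlation). Guard cell genes lay higher in 4 of 5, with MYB60 at 0.90 (SE 0.54) and SLAC1 at 0.96 (SE 0.67, adjusted p = 0.00791 and 0.177 with an estimated correlation), and xylem and procambium genes in 11 of 13 (adjusted p = 0.0268 and 0.601 with an estimated correlation). Epidermis genes lay lower in 6 of 9 (adjusted p = 0.0208 and 0.498 with an estimated correlation). edgeR called 0 genes, with 51 at an unadjusted p under 0.05 where 985 would be expected by chance, and DESeq2 called 0. With each library left out in turn, the senescence median ran from -1.08 (without p35S mock replicate 1) to 0.37 (without p35S mock replicate 2), the early wound median from -2.77 (without pSUC2 mock replicate 2) to 0.46 (without p35S mock replicate 1) and the epidermis median from -0.36 (without p35S mock replicate 1) to -0.01 (without pSUC2 mock replicate 2). Without pSUC2 mock replicate 1 the medians were 0.35 for chaperone, -0.17 for xylem, -0.02 for Aux/IAA and 0.20 for guard cell genes, and without pSUC2 mock replicate 2 they were -1.02, 0.51, -0.44 and 0.65.

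Between pSULTR22 and p35S, SULTR2;2 stood at 42.2 ± 15.2 against 16.9 ± 5.97 CPM (1.32, SE 0.44), and it was the only bundle sheath member to pass adjusted over the list alone. All 4 members of that list lay higher (median 1.16, camera adjusted p = 0.000598, adjusted p = 0.133 with an estimated correlation). Of these, SULTR2;2 is also in the companion cell and sulfate lists and MYB76 in the aliphatic glucosinolate list, so these lists are not independent of each other. Of 24 companion cell and sieve element genes 13 lay higher and 11 lower (median 0.30, adjusted p = 0.00269 and 0.355 with an estimated correlation). Among the higher were NAKR1 at 28.9 ± 18.3 against 6.79 ± 0.852 CPM (2.09, SE 0.76), PP2-A1 at 1.96 (SE 0.76), SULTR2;1 at 171 ± 37.1 against 85.1 ± 16.5 CPM (1.01, SE 0.39) and SUC2 at 2.48 (SE 1.02). RPL18, the only member of its family kept in the lists, stood at 1.19 (SE 0.53), and at 0.29 without pSULTR22 mock replicate 1. The phloem parenchyma list (median 0.98, adjusted p = 0.00766 and 0.133 with an estimated correlation) was led by SWEET11 at 1.36 (SE 0.59). Sulfate genes lay higher in 10 of 11 (median 1.01, adjusted p = 0.000182 and 0.345 with an estimated correlation), with APR2 at 1.18 (SE 0.72). All 15 aliphatic glucosinolate genes lay higher (median 1.25, adjusted p = 1.08e-07 and 0.355 with an estimated correlation), with SOT18 at 2.1 (SE 0.86). So did 9 of 10 indolic genes (adjusted p = 0.00316 and 0.133 with an estimated correlation). MYB34 stood at 36.7 ± 27.4 against 9.42 ± 0.316 CPM (1.96, SE 0.56) and passed adjusted over the list alone. Of 42 photosynthesis genes 33 lay higher (adjusted p = 0.0408 and 0.677 with an estimated correlation). All 9 epidermis genes lay lower (median -0.77, adjusted p = 4.33e-07 and 0.133 with an estimated correlation), with ABCG12 at 83.5 ± 3.54 against 164 ± 54.9 CPM (-0.98, SE 0.49), and 7 of 9 senescence genes did (adjusted p = 0.00337 and 0.345 with an estimated correlation). edgeR called 0 genes, with 354 at an unadjusted p under 0.05 where 985 would be expected by chance, and DESeq2 called 18 (16 higher and 2 lower). Without pSULTR22 mock replicate 1 the medians were -0.23 for aliphatic, -0.37 for photosynthesis, -0.08 for companion cell, -0.04 for phloem parenchyma, 0.64 for bundle sheath, 0.38 for sulfate, 0.41 for indolic and -0.51 for epidermis genes, and without pSULTR22 mock replicate 2 they were 1.97 for aliphatic, 0.75 for photosynthesis and -1.26 for epidermis genes. The senescence median was 0.34 without p35S mock replicate 2 and -1.25 without p35S mock replicate 1.

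Between pSULTR22 and pSUC2, the lines whose RNA the labels describe as from phloem, SUC2 stood at 559 ± 521 CPM in pSULTR22 against 70.0 ± 16.6 CPM in pSUC2 (3.00, SE 1.04), NAKR1 at 2.25 (SE 0.76) and SULTR2;1 at 1.08 (SE 0.39). RPL18 stood at 1.55 (SE 0.54), and at 0.68 without pSULTR22 mock replicate 1. SWEET11 was at 1.56 (SE 0.60) and SWEET12 at 31.0 ± 3.51 against 14.1 ± 9.67 CPM (1.13, SE 0.51), in a phloem parenchyma list of which all 4 members lay higher in pSULTR22 (median 1.34, camera adjusted p = 0.0037, adjusted p = 0.253 with an estimated correlation). Bundle sheath genes, which include SULTR2;2 and MYB76 of other lists, lay higher in 4 of 4 (adjusted p = 0.0042 and 0.335 with an estimated correlation). The same held for aliphatic glucosinolate genes in 14 of 15 (median 1.23, adjusted p = 1.02e-05 and 0.565 with an estimated correlation) and photosynthesis genes in 31 of 42 (adjusted p = 0.0443 and 0.719 with an estimated correlation). Epidermis genes lay lower in 8 of 9 (adjusted p = 0.00626 and 0.503 with an estimated correlation). edgeR called 0 genes, with 362 at an unadjusted p under 0.05 where 985 would be expected by chance, and DESeq2 called 11, all higher in pSULTR22. Without pSULTR22 mock replicate 1 the medians were 0.13 for phloem parenchyma, 0.59 for bundle sheath, -0.35 for aliphatic, -0.27 for photosynthesis and -0.19 for epidermis genes. Without pSULTR22 mock replicate 2 they were 0.85 for photosynthesis and -1.03 for epidermis genes, and the aliphatic median was 2.01 without pSUC2 mock replicate 1.

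The TMV effects of the lines were compared with each other by interaction terms. The log2 fold change after TMV lay higher in pSUC2 than in p35S for 8 of 9 early wound and handling genes (median difference 1.81, camera adjusted p = 0.00117, adjusted p = 0.644 with an estimated correlation). It did so for 8 of 9 senescence genes (median 1.09, adjusted p = 0.00117 and 0.644 with an estimated correlation) and for 35 of 42 photosynthesis genes (median 0.52, adjusted p = 0.000888 and 0.659 with an estimated correlation). RNA silencing genes lay lower in this difference in 15 of 17, xylem and procambium genes in 10 of 13 and hypoxia genes in 7 of 7 (adjusted p = 0.0199, 0.00711 and 0.0199, and 0.644 each with an estimated correlation). Between pSULTR22 and p35S, 9 of 9 early wound genes, 8 of 9 senescence genes and 8 of 9 epidermis genes lay higher (adjusted p = 0.00822, 0.00503 and 0.000745, and 0.793 each with an estimated correlation). Between pSULTR22 and pSUC2, 32 of 42 photosynthesis genes lay lower (adjusted p = 0.0286 and 0.974 with an estimated correlation). For single genes edgeR called 0 differences in each of the 3 interactions, and DESeq2 called 0 in each. At an unadjusted p under 0.05 there were 291, 71 and 180 genes, where 985 would be expected by chance in each. Adjusted over the list alone, SEN1 (AT4G35770) was the only list member to pass, between pSUC2 and p35S (2.48, SE 0.65). SEN1 did not pass over all genes, and the adjustment over its list does not cover the other lists and interactions. For no gene is an effect seen in 1 line and not in another thus shown to differ between them. With each library left out in turn, several of these list medians changed sign. Between pSUC2 and p35S the early wound median ran from -0.34 (without pSUC2 TMV replicate 1) to 4.06 (without pSUC2 mock replicate 2) and the senescence median from -0.08 (without p35S mock replicate 2) to 1.8 (without pSUC2 mock replicate 1). The photosynthesis median was 0.21 without pSUC2 TMV replicate 1, the RNA silencing and hypoxia medians were -0.23 and -0.49 without pSUC2 mock replicate 1, and the xylem median was -0.37 without p35S TMV replicate 2. Between pSULTR22 and p35S the early wound median ran from -0.08 (without pSULTR22 TMV replicate 1) to 2.42 (without pSULTR22 mock replicate 2), the senescence median from -0.05 (without p35S mock replicate 2) to 1.42 (without p35S mock replicate 1) and the epidermis median from 0.32 to 1.0 (without pSULTR22 mock replicates 1 and 2). Between pSULTR22 and pSUC2 the photosynthesis median ran from -1.18 (without pSULTR22 TMV replicate 1) to 0.18 (without pSULTR22 mock replicate 1).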

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

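The tests of depth, of the clock gene score, of the iron genes, of the table forms, of swapped labels and of the 18S ribosomal RNA locus were chosen only after the results were seen.

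The first pattern is the 8 genes that rose on average in infected leaves. Of 100 regroupings of the libraries within their lines, 2 gave at least 8 genes, the real grouping included. The highest other grouping gave 75, which points to a structure of the samples. It set 3 infected libraries (replicate 1 of each line) with the mock libraries p35S 1, pSUC2 2 and pSULTR22 2 against the rest. Libraries that fall into such clusters are not interchangeable, and regroupings that mix clusters have a wide spread and so few calls. The regroupings therefore cannot exclude chance. Lower depth of the infected libraries is argued against by thinning to the smallest library, after which 7 of the 8 genes passed (ERD2, AT1G56410, did not). With the clock gene score as a covariate 8 of 8 passed, which argues against an effect of harvest time that runs along that score. The score mainly sets 3 mock libraries (3.31 to 4.42) apart from the other 9 libraries (-3.52 to -0.32). Other differences in harvest time between infected and mock leaves are therefore not excluded. RNA or library quality cannot be told apart from infection, because the share of mapped reads on exons was lower after TMV: with that share as a covariate 0 of the 8 passed, the median log2 fold change went from 3.71 to 2.49, and the SE of FRO3 grew from 0.32 to 0.77 as its fold went from 2.33 to 1.05, while bHLH38 went from 4.34 (SE 0.47) to 4.53 (SE 1.36). A response to the virus therefore stays open beside a difference in RNA quality, such other differences in harvest time, and chance.

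The second pattern is that libraries were closest to libraries of other groups. Pairs with more distant clock gene scores were more distant over the other genes (Mantel r = 0.72, rho = 0.77, permutation p = 0.00026, adjusted p = 0.0013 over 5 measures). Without the 2 farthest libraries r was 0.63. Leaves harvested at different times of day could give this, though no harvest time is given. Of the clock genes outside the score, CCA1 and LUX went with that reading, and ELF4 did not in pSULTR22 mock 1. In p35S mock 2, pSUC2 mock 1 and pSULTR22 mock 1, CCA1 stood at 12.54, 19.55 and 16.87 CPM (1.44 to 1.49 in the other mock libraries). LUX stood at 17.12, 10.72 and 42.64 CPM (65.6 to 91.65). LHY differed less, at 2.58, 2.55 and 3.52 CPM (1.28 to 2.04). The evening gene ELF4 stood at 7.58, 3.52 and 92.76 CPM (33.23 to 46.41). The scores fall into clusters, 3.31 to 4.42 in p35S mock 2, pSUC2 mock 1 and pSULTR22 mock 1 and -3.52 to -0.32 in the other 9 libraries; within those 9 r was 0.46 (rho = 0.41, exact permutation p = 0.019, adjusted p = 0.048), within the 6 mock libraries 0.82 (exact permutation p = 0.0014) and within the 6 infected libraries 0.22 (exact permutation p = 0.27). The share of mapped reads on exons gave r = 0.41 (rho = 0.32, permutation p = 0.019, adjusted p = 0.032), but -0.05 within mock and 0.23 within infected libraries (exact permutation p = 0.56 and 0.20), and it cannot be told apart from treatment. The form of the deposited tables gave r = 0.01 (rho = -0.01, permutation p = 0.36). The 4 tables without an RPKM above 0 at 0 exon reads were p35S mock 1, pSUC2 mock 2 and both pSULTR22 mock libraries. Form thus went partly with treatment and with the close mock libraries, so this test cannot exclude it.

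The third pattern is that SUC2 reads were highest in pSULTR22 libraries and not in those labelled pSUC2. Labels of the pSUC2 and pSULTR22 lines swapped cannot be told apart from labels that are right. The lowest SULTR2;2 value labelled pSULTR22 was 1.18 times the highest labelled pSUC2, but SULTR2;2 is also in the companion cell list, and its reads cannot be told from those of its antisense gene. Why the pSUC2 libraries held no more SUC2 reads than p35S stays open, and no biological explanation was tested.

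The other results are given as values. The TMV effects of the lines differed for the lists below by the interaction test with the preset correlation, and for none of these with an estimated correlation. Between pSUC2 and p35S the median difference was 1.806 for early wound, 1.089 for senescence, 0.521 for photosynthesis, -0.585 for RNA silencing, -0.769 for xylem and procambium and -0.956 for hypoxia genes. Between pSULTR22 and p35S it was 1.4 for early wound, 0.944 for senescence and 0.555 for epidermis genes, and between pSULTR22 and pSUC2 it was -0.449 for photosynthesis genes.

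Reads of genes outside exons, which only the alternative with all gene reads used, were 12.14 ± 5.87% of gene reads in infected and 3.52 ± 1.78% in mock libraries (exact permutation p = 0.004329, adjusted p = 0.00577, n = 6 each). Most of the difference was the locus of the 18S ribosomal RNA, AT3G41768, which has no exon reads in the tables. With that locus left out the shares were 2.63 ± 1.23% and 2.16 ± 0.67% (exact permutation p = 0.4242, n = 6 each).

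Of 222 named genes 11 had all libraries moving one way in 1 line and the opposite way in another. By chance 31 would be expected for genes fixed in advance and libraries that vary independently. The named genes were picked in part by a small p in these same comparisons, so setting 11 against 31 is no test. The interaction did not pass over all genes for any of the 11 (edgeR adjusted p = 1). SEN1 (AT4G35770) passed between pSUC2 and p35S adjusted over its list alone. The largest distance between the log2 fold changes of the lines was 3.48 for CML38, 2.75 for IAA5, 2.48 for SEN1 (AT4G35770), 2.32 for ORE1, 2.29 for ALD1 and 2.13 for ROF2. It was 1.5 for SUS4, 1.38 for HRE1, 1.02 for AGO2, 0.94 for EDS5 and 0.51 for TOM3.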

How the results depend on the processing

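The alternatives with all gene reads, thinning, library weights, the clock gene score, libraries left out together and the crossed block were chosen only after the data were seen. Of the counts of called genes, 253 values were within 1.5 times of the main count and 28 were not, and for these the cause was not tested except where stated. The main count was 0 in every comparison but the average over the lines, so most of the 253 set 0 against 0. They say little about the 8 genes called on average, whose count left that range with any 1 library left out. DESeq2 called 9 genes for TMV in p35S, 164 in pSUC2, 12 in pSULTR22 and 1471 on average, and 18 and 11 between pSULTR22 and p35S or pSUC2 in mock leaves; on simulated data it made more false calls than edgeR. Without a filter edgeR called 3 genes in pSUC2 and 429 on average, where the prior degrees of freedom rose from 5.38 to 14.64. With only the groups compared it called 1 gene in pSUC2. On average it called 3 genes with a replicate block within each line, 1535 with a crossed block (660 higher and 875 lower), 4 with library weights in limma-voom, 18 with the clock gene score, 0 with infected libraries of replicate 2 only (4486 at an unadjusted p under 0.05), 0 with pSUC2 libraries left out (1441) and 0 with the 3 mock libraries of high clock gene score left out (2039). Leaving out each library gave 0 to 19 genes on average and 0 in the other 9 comparisons, where a lone library is assumed to vary like the others. Correlations of replicate differences between groups ran from -0.77 to 0.53, with 0.14, 0.41 and 0.44 among the infected groups. They do not show that replicate numbers pair all libraries, and the months of growth cannot be read from them. Several list medians changed sign with 1 library left out. Of the values of single genes and list tests, 17698 kept their side of the threshold and stayed near their main value, 905 moved, 71 passed the threshold and 194 no longer did. At this depth and spread, edgeR found 6% of simulated 4-fold changes within pSUC2 and 70% on average, so uncalled genes are not shown to be unchanged.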

Other observations

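The iron and clock gene lists of this part, and their tests, were chosen only after the results were seen. Because bHLH38, bHLH39, BHLH101 and FRO3 rose, other genes known to be induced by iron deficiency were read on average over the lines. Of 13 measured, 12 had a positive log2 fold change. BHLH100, a close relative of bHLH38, stood at 3.95 (SE 0.75), the small peptide genes AT1G47400 and AT1G47395 at 2.81 each (SE 0.76 and 0.68), the hemerythrin-domain ubiquitin ligase gene BTS at 1.43 (SE 0.29), and the zinc and nicotianamine transporter gene ZIF1 at 1.38 (SE 0.29). OPT3, also in the companion cell list, stood at 0.95 (SE 0.28). Of 9 genes of iron storage and iron cofactors, 8 had a negative one. The ferric reductase gene FRO6 stood at -1.93 (SE 0.38), the metal transporter gene YSL1 at -2.10 (SE 0.52), and the ferritin genes FER4 and FER1 at -1.89 (SE 0.52) and -0.98 (SE 0.44). None of these genes passed over all genes with edgeR (smallest adjusted p = 0.117).

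A hypothesis is that the leaf iron deficiency response is raised in infected leaves. The induced genes had a median of 1.38 and stood apart from the other genes (camera p = 3.48e-08, p = 0.0261 with an estimated correlation). The storage and cofactor genes had a median of -1.22 (camera p = 0.00106, p = 0.0898 with an estimated correlation), so the test set for the pair of lists, that both pass with an estimated correlation, was met by the first list only. In p35S, pSUC2 and pSULTR22 the medians of the induced list were 0.97, 1.5 and 1.4 and those of the storage list -0.71, -0.72 and -2.05. The storage list leaned on single mock libraries: YSL1 stood at 109.24 CPM in pSULTR22 mock 1 against 4.77 to 16.63 in the other mock libraries, and FER1 at 218.37 against 24.74 to 75.96. FER4 and FRO6 were highest in p35S mock 2, pSUC2 mock 1 and pSULTR22 mock 1 (26.54 to 44.69 and 330.14 to 567.48 CPM, against 6.21 to 8.92 and 146.92 to 211.4 in the other 3). Without these 3 libraries the medians were 1.2 for the induced genes (camera p = 1.491e-08, p = 0.05654 with an estimated correlation) and -0.8 for the storage genes (camera p = 0.008931, p = 0.0727 with an estimated correlation), and the storage median in pSULTR22, with 1 mock library left, was -0.8. The hypothesis may hold, but these values do not decide it, and leaf iron was not measured.

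Clock genes that peak from morning to afternoon lay lower on average in 5 of 5, with PRR9 at -3.29 (SE 1.33) and PRR5 at -2.0 (SE 0.83). Their median was -1.43, and as a list they did not stand apart from the other genes by camera. Those that peak in the evening had a median of 0.22, with LUX at 0.70 (SE 0.54) and TOC1 at 0.00 (SE 0.36). The difference follows 3 mock libraries, p35S 2, pSUC2 1 and pSULTR22 1, whose clock gene scores were 3.67, 4.42 and 3.31, while the other 3 mock libraries had -3.24, -3.37 and -3.52. Without those 3 libraries the direction reversed: all 5 morning to afternoon genes lay higher after TMV (median 0.79), and the evening median was -0.28. The score is built from PRR9, PRR7 and PRR5 of the first list and TOC1 and BOA of the second. The part of these 3 libraries and the reversal without them thus follow from that choice and test nothing. The locus of the 18S ribosomal RNA, AT3G41768, which makes up most gene reads outside exons in infected libraries, took 9.80 ± 5.35% of gene reads in infected and 1.39 ± 1.61% in mock libraries (exact permutation p = 0.004329, n = 6 each).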
